A study of Arabidopsis thaliana with 9 samples.

How the data were processed

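Total RNA from whole Arabidopsis thaliana seedlings, roots included, was hybridised to Affymetrix ATH1 arrays, 1 sample per array. Seedlings of the accessions (natural lines, called ecotypes in the labels) Col-0 and WS were grown for 10 days on Gamborg's medium with 0.7% agar. Plates had been stratified for 3 days and stood in continuous light of 60 to 80 microE at 22 °C, and seedlings then spent 24 h at 4 °C or, as the mock treatment, in a fresh chamber at 22 °C. The 9 arrays used comprised 2 of Col-0 at 22 °C, 5 of Col-0 at 4 °C and 2 of WS at 4 °C. Of the 5 cold Col-0 arrays, 2 carried the name set 4 in their titles and 3 carried no set name. The titles of the WS arrays carried q6ws and q8ws, which the labels do not explain, and these arrays were treated as 2 replicates. No WS array at 22 °C was among the samples used, so the cold response within WS was not tested.

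The authors made the values by RMA with the R package affy, and the deposited values are log2 signals, 1 per probe set and array. The version of either tool is not given in the labels. Array medians lay between 5.81 and 6.06. Detection calls were not used here, so no limit of detection was set, and the number of arrays limits the precision. Of 22810 probe sets, 64 control probe sets were left out and 22746 were tested. Gene names came only from the probe annotation and the RefSeq gene table for TAIR10.1. They gave a single gene for 13513 probe sets, several genes for 503, and no gene for 8730, which were tested but are not named here. The single-gene probe sets covered 13356 genes, and 146 of these had more than 1 probe set. The probe set with the highest mean over the 9 arrays stood for a gene.

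Differences between groups were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) to all 9 arrays with a mean per group. P-values were adjusted by Benjamini-Hochberg over all probe sets tested. A probe set was called at an adjusted p under 0.05 and an absolute log2 fold of at least 1, and the values after ± are standard deviations across arrays unless given as SE. The contrasts were Col-0 at 4 °C minus Col-0 at 22 °C, WS at 4 °C minus Col-0 at 4 °C, WS at 4 °C minus Col-0 at 22 °C, and set 4 minus the other cold Col-0 arrays. The last contrast used 4 group means. Residual degrees of freedom were 6, and 5 for the set contrast. The labels do not say whether arrays of a group came from separate cultures, so p-values measure only the spread between these samples. Shared calls were set beside the number that independent lists of the same size give, beside 100 simulations of unchanged groups that share the same arrays (the share of WS arrays beyond the 22 °C arrays in them was added after the data were seen), and, for calls shared by the cold contrast and the WS against Col-0 contrast, Fisher's exact test (two-sided).

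Gene lists were tested with camera from limma at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 26 lists with at least 3 measured genes. Camera with an estimated correlation and fry were run beside it. The contrasts, thresholds, 21 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Of those 21 lists, 4 had at least 3 measured genes and 11 had 1 or 2, which are given by gene. The other 6 had none that the annotation listed with a probe set of its own (abscisic acid response, salicylic acid and pathogen response, membrane lipid metabolism, resistance genes, flowering time, seed storage markers) and gave no result. In all, 35 of the 326 members of these 21 lists were measured, meaning that the annotation listed a probe set for that gene alone. The rest may lie among the 8730 tested probe sets with no listed gene, so the array need not lack them. A further 22 lists were added after the annotation, the array summaries and the correlations between arrays had been seen, but before any test. The 2 lists that were to be drawn from gene descriptions (resistance proteins and cytosolic ribosomal proteins) were not analysed here. The results of 1 added list are not reported here.

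The rule for named genes took, for the cold and the WS against Col-0 contrasts, the 10 highest and 10 lowest called genes whose arrays did not overlap between groups. It also took up to 4 called and 2 other members of each list with the largest fold, and the 3 with the largest WS difference in each combination of directions called in both contrasts. The rule further named CBF1, CBF2, CBF3, RD29A, COR15A and COR47 in every contrast. Only COR15A and COR47 of these had a listed probe set of their own, so the others are not reported. Some are summarised. COR27, AT4G33980, DFR and UGT78D2 were named to complete lists of at most 6 genes, TIL, DI21 and HIS1-3 to describe their list, AT1G53540 as its list's lone member, and the pairs of neighbouring genes because they were few. These were chosen after their values were seen.

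The pipeline was tested on simulated data with 100 changed probe sets at each size. At a log2 fold of 1.5 it recovered 97.0% in the cold contrast, 97.0% in WS against Col-0, 94.0% in WS at 4 °C against Col-0 at 22 °C and 100.0% in the set contrast. At a log2 fold of 3 it recovered 100.0%, 99.0%, 100.0% and 100.0% in the same order, and it called 3, 4, 2 and 5 unchanged probe sets. Lists of 10 genes shifted by 0.5 were found in 100% of draws and unchanged lists in 3%. The simulated genes varied independently of one another, while the COR and flavonoid lists had an estimated correlation of 0.68. The 3% is therefore not the rate of false calls for lists of correlated genes.

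Alternatives were a fit to the compared arrays only, eBayes with trend and robust, a minimum log2 signal of 6 on at least 2 arrays (12254 probe sets, 53.9%), quantile normalization, median centring, no fold minimum, 1 probe set per gene, set 4 as a term, set 4 left out or alone, the replicate number as a block, and each array left out in turn. Leaving out arrays for the gene lists and shared calls, one exchange of cold Col-0 arrays between contrasts, and a different 22 °C array for each contrast, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.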

Results

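The arrays measured transcript levels in 10-day-old Arabidopsis thaliana seedlings of Col-0 and WS after 24 h at 4 °C (5 and 2 arrays) and of Col-0 kept at 22 °C (2 arrays). The title names conserved cold-responsive expression signatures of the 2 accessions as the aim. Median log2 signals lay between 5.81 and 5.88, except 6.06 in replicate 3 of cold Col-0. Across probe sets, which are not independent replicates, cold Col-0 arrays correlated with one another at 0.979 to 0.993, with WS at 0.965 to 0.981 and with the 22 °C arrays at 0.935 to 0.952. The first principal component held 56.0% of the variance and separated the 22 °C arrays from all cold arrays, and the second held 18.7%.

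Cold raised transcripts of the COR genes, cold-regulated effectors that include chloroplast stromal proteins and dehydrins, in Col-0 seedlings. COR15A rose from 7.37 ± 1.34 (SD, n = 2) to 13.43 ± 0.09 (n = 5), a 66.6-fold difference (log2 6.06, SE 0.39, limma adjusted p = 1.19e-05). This SE and p rest on the spread pooled over all groups, so they understate the wider spread at 22 °C. The same holds for COR15B and LTI30, with SDs of 1.28 and 1.54 at 22 °C. COR15B rose 43.6-fold, the dehydrin LTI30 23.0-fold and COR47 7.9-fold. These sizes depend on the 22 °C arrays: without replicate 1 or 2 the folds were 34.5 and 128.5 for COR15A, 23.3 and 81.6 for COR15B, 10.8 and 49.0 for LTI30, and 3.9 and 9.7 for COR27. Cold signals of COR15A, LTI30 and COR47 stood near the array maxima, where a ceiling would make folds too small. COR27 and AT4G33980 rose by 2.62 and 1.96 on the log2 scale, so all 6 measured COR genes rose. All 6 were also called when adjusted over the list alone, which follows where every member is already called and adds no support. The list's median log2 fold was 3.76 (camera adjusted p = 2.27e-06, and adjusted p = 0.335 with an estimated correlation), and fry gave an adjusted p of 0.000325.

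Among all named genes, AT1G16850 had the highest fold with all arrays, rising from 5.60 ± 0.89 to 11.75 ± 0.11 (log2 6.15, SE 0.30, limma adjusted p = 5.02e-06). It had 45.9-fold and 110.0-fold without replicate 1 or 2 at 22 °C, and without replicate 2 COR15A stood above it (128.5-fold). AT1G51090 (37.9-fold), AT3G55580 (26.5-fold, the lone measured member of the cold shock and RNA chaperone list), the vacuolar processing enzyme gene BETA-VPE (25.2-fold), AT1G80130 (24.5-fold), LEA4-5 (20.5-fold) and the glutathione transferase gene GSTU25 (20.5-fold) followed. Without replicate 1 or 2 at 22 °C, LEA4-5 had 11.8-fold and 35.6-fold, and GSTU25 13.1-fold and 32.1-fold. The lowest folds belonged to AT4G27450 (log2 -4.99) and to EXPA8, an expansin that loosens cell walls. EXPA8 fell from 9.65 ± 0.32 to 4.66 ± 0.15 (log2 -4.98, SE 0.17, limma adjusted p = 9.14e-07). AT3G06070, whose cold mean of 3.43 was dim, and AT1G51400 fell as well (log2 -3.95 and -3.88). The clock gene GI rose 5.0-fold. In their lists of 1 or 2 measured genes, GI, STZ, AT3G55580 and EXPA8 were also called when adjusted over the list alone. An adjustment over so few genes could not end these calls, so this adds no support. The zinc finger factor STZ, the lone measured early cold transcription factor, rose 2.5-fold (limma adjusted p = 0.0263), but this call was lost without replicate 1 at 22 °C (adjusted p = 0.29) and without replicate 1 (0.0541) or 3 (0.0515) of cold Col-0.

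All 5 measured genes of the flavonoid and anthocyanin list rose: AT5MAT 6.1-fold, UF3GT 4.4-fold, UGT78D2 3.8-fold, AT4G14090 3.1-fold and DFR by 1.51 on the log2 scale. Adjusted over the list alone, 5 were called, which follows from their calls over all probe sets. The list had a median log2 of 1.92 (camera adjusted p = 0.00132, and adjusted p = 0.335 with an estimated correlation). AT4G14090 was not called without replicate 1 (adjusted p = 0.0628) or 2 (0.123) at 22 °C. UF3GT was lost without replicate 2 at 22 °C (0.0757), and DFR without that array (0.26) or replicate 3 of cold Col-0 (0.0537), or with set 4 as a term (0.0603).

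Of 12 genes for RNA polymerases I and III and nucleolar assembly, which make ribosomal and transfer RNA and assemble ribosomes, 6 rose and all 12 had positive folds (median log2 1.02, camera adjusted p = 3.4e-06, and adjusted p = 0.335 with an estimated correlation). YAO rose 6.1-fold, the polymerase I subunit genes NRPA1 and NRPA2 rose 4.1-fold and 3.1-fold, and IMP4 rose 3.3-fold. The set 4 arrays had a median log2 difference of -0.40 from the other cold Col-0 arrays on this list. Of 14 late embryogenesis abundant and dehydration-related genes, 4 of which are also COR genes, 7 rose and 1 fell (median log2 0.76, camera adjusted p = 0.0022, and adjusted p = 0.335 with an estimated correlation). TIL rose by 1.87 on the log2 scale (limma adjusted p = 3.2e-05), and DI21 rose too (limma adjusted p = 0.00143). The histone H1 gene HIS1-3 fell by 1.11 on the log2 scale (limma adjusted p = 0.039), with log2 folds of -1.93 and -0.29 without replicate 1 or 2 at 22 °C. HIS1-3 was not called without replicate 2 at 22 °C or without either WS array. Its call also ended when any cold Col-0 array but replicate 3 was left out (limma adjusted p = 0.058 to 0.0788), and with set 4 as a term (0.062) or left out (0.0835).

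Nuclear photosynthesis and chlorophyll genes had lower signals in the cold: 6 of 22 fell and none rose (median log2 -0.50, camera adjusted p = 1.85e-06, and adjusted p = 0.335 with an estimated correlation). The antenna gene LHCB4.2 fell with a log2 fold of -1.86, CHLM of chlorophyll synthesis with -1.62, and NdhL and NdhN with -1.56 and -1.17. In the shorter light harvesting and Rubisco list LHCB4.2 was the 1 of 4 called, and the same 1 when adjusted over the list alone (camera adjusted p = 0.0106). With an estimated correlation the adjusted p = 0.335, and without dim probe sets it was 0.0755.

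Autophagy genes were lower as well, with 4 of 10 called (median log2 -0.82, camera adjusted p = 3.92e-05, and adjusted p = 0.335 with an estimated correlation). ATG8E, ATG8F and ATG8C, whose products coat autophagosomes, fell with log2 folds of -2.73, -2.03 and -1.43. APG8H fell by 1.05, and its fold was under the minimum without replicate 2 at 22 °C (log2 -0.85) or replicate 2 of cold Col-0 (log2 -0.99). Of 10 genes of root endoplasmic reticulum bodies, jacalins and the root hair wall, 3 fell (median log2 -0.63, camera adjusted p = 0.0141, and adjusted p = 0.335 with an estimated correlation). JAL22, JAL33 and NAI2 had log2 folds of -2.01, -1.62 and -1.39. The root markers PYK10 and EXPA7 had log2 folds of -0.37 and 0.17 (adjusted p = 0.3 and 0.787).

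**Figure D1:**
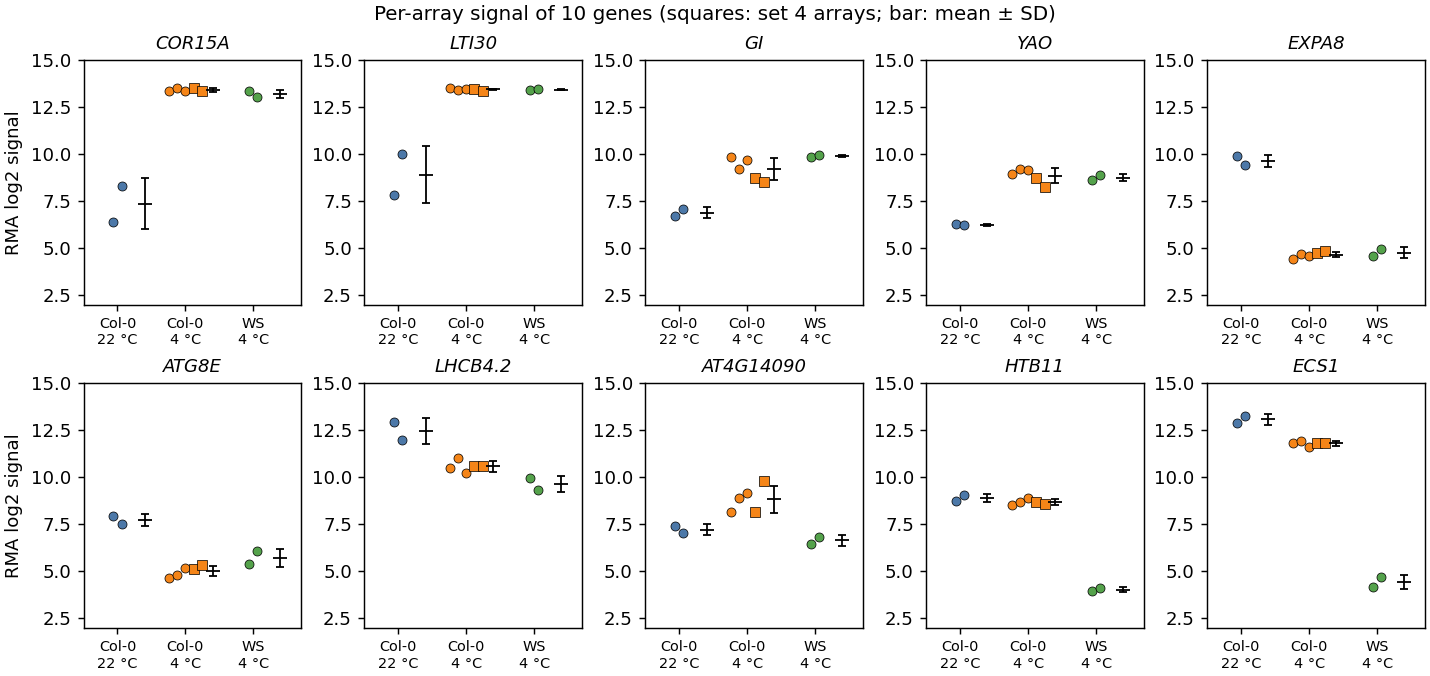
Per-array RMA log2 signal of 10 genes (y axis) in Col-0 at 22 °C (n = 2), Col-0 at 4 °C (n = 5) and WS at 4 °C (n = 2), with mean ± SD beside the points and squares for set 4. COR15A lay near 13 on all 7 cold arrays, and ECS1 was at 4.42 in WS against 11.81 in cold Col-0.

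The next 7 families were not called as lists in the cold, and 6 of them had calls in both directions. Among 19 sugar transporters 6 rose and 3 fell (camera adjusted p = 0.831), with SWEET13 at 11.2-fold, SWEET4 at 7.0-fold, TMT2 at 4.7-fold and SFP1 at a log2 fold of -2.16. Starch enzymes had 2 of 7 genes called, both higher, the ADP-glucose pyrophosphorylase subunits APL3 (7.5-fold) and APL4 (7.4-fold), with a list p of 0.0955 (camera, adjusted). Expansins and xyloglucan endotransglucosylases had 3 of 27 called higher, XTH20 (log2 3.09) and EXLA2 (log2 2.53) among them, and 3 lower, EXPA8 and EXPB3 (log2 -1.77) among them (camera adjusted p = 0.7). Chaperones had 5 of 13 higher and 2 lower (0.34), with Fes1A at log2 1.82, Hsp70-2 at 1.72, Hop2 at 1.38 and Fes1B at -1.75. UGT glycosyltransferases had 7 of 47 higher and 5 lower (0.459), UGT78D3 (log2 2.90) and UGT84A3 (log2 2.20) among the higher. GSTU glutathione transferases had GSTU25 higher and 2 of 11 lower (0.729), GSTU18 at log2 -3.07 among them. CYP71B cytochromes P450 had CYP71B26 (log2 1.61) higher and 4 of 19 lower (0.0955), CYP71B5 (log2 -1.80) among them.

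The remaining lists were not called in the cold by camera. Adjusted p was 0.121 for 69 plastid-encoded genes, where rpoB was higher (log2 1.54) and rpl33 lower (log2 -1.02), and 0.121 for 3 ribosomal protein genes, none called, with no further call when adjusted over the list alone. It was 0.0955 for 7 iron deficiency regulators, with bHLH34 higher (log2 1.02) and bHLH104 lower (log2 -1.07), and 0.529 for 4 stomatal lineage genes, with STOMAGEN lower (log2 -1.14). It was 0.956 for tubulins, with TUB9 higher (log2 1.17), 0.956 for endoplasmic reticulum protein folding (1 of 13 lower), 0.869 for H2B histones, aurora kinases and mitotic checkpoint genes (0 of 14), 0.956 for auxin genes (0 of 16), 0.808 for jasmonate and wound genes (0 of 9) and 0.7 for pseudogenes (2 of 989 higher, 2 lower). The jasmonate-responsive PDF1.2 had a log2 fold of -2.53 (limma adjusted p = 0.0667), and THI2.1 had 0.10. The fold of PDF1.2 depended on the 22 °C arrays, with log2 -3.88 and -1.18 without replicate 1 or 2. Without the first set 4 array PDF1.2 was called (limma adjusted p = 0.0229), as it was when adjusted over the list alone. The calls of rpoB (0.053 to 0.175) and STOMAGEN (0.0573 and 0.0558) ended without either 22 °C array, and that of rpoB also without replicate 1 of cold Col-0. Those of rpl33 (log2 -0.97 to -0.95 without replicate 2 at 22 °C, replicate 1 of cold Col-0 or the second set 4 array) and bHLH34 (log2 0.95 and 0.99 without replicate 1 or 3 of cold Col-0) fell under the fold minimum. With the set 4 arrays left out, or set 4 as a term, bHLH104 (just short of the minimum), rpl33 (log2 -0.97) and STOMAGEN (log2 -0.95) were not called. Single members of small lists had log2 folds of -0.64 (ATSPS4F, sucrose synthesis), 0.18 (AT1G53540, heat shock), 0.02 and 0.13 (AUR1 and AUR2, cell cycle), -0.04 and -0.24 (AOP3 and BCAT4, glucosinolates), and 0.02 (IAA29, beside EXPA8 in growth), none called, though ATSPS4F was with set 4 as the sole cold arrays (log2 -1.01, adjusted p = 0.0455). AOP3, IAA29, THI2.1 and AT1G53540 had signals of only 3.45 to 4.18 on the Col-0 arrays. A fold near 0 at such dim levels need not mean an unchanged transcript. The reference genes AT4G34270 and AT2G28390 had log2 folds of -0.43 and 0.31, not called. Medians and means differed in sign for the GSTU, endoplasmic reticulum folding and jasmonate and wound lists, with camera direction following the median in the first 2 and the mean in the third.

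In total 2721 of 22746 probe sets (12.0%) were called in the cold by limma, 1335 higher and 1386 lower, and 1463 of them named a single gene. Over 4-fold, 288 were higher and 267 lower. Only 2 arrays stood for 22 °C, and COR15A differed between them by more than it did among the 5 cold arrays (SD 1.34 against 0.09).

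WS seedlings at 4 °C were compared with Col-0 at 4 °C for differences between the accessions after the same treatment. No COR gene was called: COR15A had a log2 difference of -0.22 (SE 0.39, limma adjusted p = 0.842), COR15B -0.15 and COR47 0.02, and 0 of 6 were called, also when adjusted over the list alone (median log2 -0.02, camera adjusted p = 0.908). COR15A, LTI30 and COR47 had means of 13.43, 13.44 and 13.46 in cold Col-0, close to the array maxima of 13.84 to 14.09, so small differences there say little. ECS1, which encodes a cell wall protein, was 167.7-fold lower in WS, at 4.42 ± 0.37 (SD, n = 2) against 11.81 ± 0.12 (n = 5), with a limma adjusted p of 5.66e-08. AT1G66100 (log2 -5.80), AT3G47250 (32.1-fold), the histone H2B gene HTB11 (-4.65), AT1G73490 (-4.48), AT2G40010 (-4.32), AT5G03350 (-4.24) and AT1G11280 (-3.83) were also lower. The WS means of AT1G66100 (3.56), AT3G47250 (3.23) and AT2G40010 (3.47) were dim (under 3.88), and signal over background was not assessed, so the sizes of their differences are uncertain. HTB1, another H2B gene, was 2.3-fold higher. Higher in WS were AT2G15560, at 9.19 ± 0.93 against 4.53 ± 0.12 (25.3-fold, SE 0.28 in log2, limma adjusted p = 2.69e-05, and 39.8-fold and 16.1-fold without WS replicate 1 or 2), AT5G38020 (15.7-fold), AT5G15360 (13.6-fold), AT4G23680 (8.9-fold) and AT2G28400 (8.8-fold).

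The flavonoid and anthocyanin genes that rose with cold in Col-0 had lower signals in cold WS. AT4G14090 was lower by a log2 of -2.19 (SE 0.42, limma adjusted p = 0.0197) and AT5MAT by -1.55 (SE 0.33, limma adjusted p = 0.0309), while UF3GT (-1.67, 0.069), DFR (-1.56, 0.08) and UGT78D2 (-0.42, 0.136) were not called, though UF3GT (0.0441) and DFR (0.046) were with set 4 left out. Thus 2 of 5 were called, and 4 when adjusted over the list alone (median log2 -1.56, camera adjusted p = 9.16e-05, and adjusted p = 0.571 with an estimated correlation), and fry gave an adjusted p of 0.057. The call of AT4G14090 was lost without WS replicate 1 (adjusted p = 0.131) or 2 (0.102). The call of AT5MAT was lost without either WS array (0.151 and 0.166) or replicate 1, 2 or 3 of cold Col-0 (0.0548 to 0.0653).

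Autophagy genes lay higher in WS than in cold Col-0, with positive differences in 10 of 10 genes (median log2 0.43, camera adjusted p = 9.16e-05, and adjusted p = 0.571 with an estimated correlation). Only ATG8H was called (log2 1.36, limma adjusted p = 0.0265), and not without WS replicate 2 (0.226), replicate 1 of cold Col-0 (0.0539) or the first set 4 array (0.0596). ATG8E had a log2 difference of 0.70 (adjusted p = 0.145). GSTU glutathione transferases had a median log2 of 0.45 with 0 of 11 called (camera adjusted p = 0.0409, and adjusted p = 0.571 with an estimated correlation). GSTU25 had 1.82 (limma adjusted p = 0.146, and called at 0.0489 without the second set 4 array) and GSTU22 had 1.54 (0.209). The GSTU list was not called without either 22 °C array (0.0556), replicate 1 of cold Col-0 (0.062) or WS replicate 1 (0.063) or 2 (0.066), nor without dim probe sets (0.245).

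Among the other lists, the P450 gene CYP71B26 was 8.8-fold lower in WS (1 of 19 CYP71B genes, camera adjusted p = 0.86), and HTB11 and HTB1 were the 2 of 14 histone and mitotic genes called (0.485). JAL33 was lower (log2 -2.85) and JAL34 higher (log2 1.19, limma adjusted p = 0.0488) among the 10 root genes (0.922), and JAL34 was not called when any array but the second set 4 array was left out (0.0541 to 0.346). XTH18 was higher (log2 1.57) and EXPA4 lower (log2 -1.20) among 27 expansins and xyloglucan endotransglucosylases (0.753), and UGT73B5 was higher (log2 1.68) among 47 UGT genes (0.884). XTH18 (0.185) and UGT73B5 (0.152) were not called without WS replicate 2. Pseudogenes had 3 of 989 lower (0.274). No member was called for plastid-encoded genes (0.967), dehydration-related proteins (0.753), sugar transporters (0.753), starch enzymes (0.255), endoplasmic reticulum folding (0.967), chaperones (0.216), tubulins (0.376), RNA polymerases I and III (0.7), photosynthesis (0.127), auxin (0.612), iron regulators (0.653), jasmonate and wound genes (0.671), stomatal lineage (0.753), light harvesting (0.428) or ribosomal proteins (0.753), camera adjusted p in parentheses. In lists of 1 or 2 genes, STZ (log2 0.86), GI (0.70), PDF1.2 (1.98), AT3G55580 (-0.40), PYK10 (0.19), EXPA7 (-0.17) and AT1G53540 (0.97, adjusted p = 0.00124, under the fold minimum) were not called, though GI was with set 4 as the sole cold Col-0 arrays (log2 1.27, adjusted p = 0.0425). AT1G53540 passed it without replicate 3 of cold Col-0 (log2 1.01) or WS replicate 2 (log2 1.02). Lists whose median and mean differed in sign were CYP71B, the root genes, sugar transporters, endoplasmic reticulum folding and plastid-encoded genes, and for the expansin list camera pointed lower while both were above 0.

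By limma 486 probe sets (2.1%) were called between WS and Col-0 after cold, 195 higher in WS and 291 lower, 272 of them naming a single gene. Over 4-fold, 28 were higher and 74 lower. Without WS replicate 2 the counts were 111 higher and 174 lower, and with each array centred on its median 264 and 289, so the excess of lower calls was small on that scale. The array's probes follow Col-0 sequence: of 10 probe sets called lower in WS with a second probe set for their gene at a Col-0 log2 signal of 6 or more, 1 was followed by it, as against 11 of 14 for cold calls (Fisher's exact test, two-sided, p = 0.00276) and 3 of 5 for calls lower in the cold (p = 0.0769). These are pairs of probe sets, and a gene with both called enters for each, so the Fisher p-values can be too small. With set 4 as the sole cold Col-0 arrays 91 probe sets were called higher and 140 lower in WS, and with set 4 left out 210 and 340.

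The signals of cold WS were set against Col-0 at 22 °C to ask whether genes called in cold Col-0 lay on the same side in WS. COR15A stood 57.3-fold above Col-0 at 22 °C (log2 5.84, SE 0.46, limma adjusted p = 4.41e-05, and 29.7-fold and 110.6-fold without replicate 1 or 2 at 22 °C) and COR47 8.0-fold above it. The SE and p of COR15A again rest on the spread pooled over all groups. Of the COR genes 6 of 6 were called higher (median log2 3.76, camera adjusted p = 1.41e-05), and so they were by necessity when adjusted over the list alone. Nuclear photosynthesis genes (6 of 22 lower, camera adjusted p = 6.91e-08), RNA polymerase I and III and nucleolar genes (5 of 12 higher, 0.000117), dehydration-related genes (7 of 14 higher, 0.00202) and light harvesting genes (1 of 4 lower, 0.0117) were called too. With an estimated correlation the adjusted p = 0.38 for all 5 lists, and light harvesting was at 0.107 without dim probe sets. The flavonoid list (1 of 5 higher, camera adjusted p = 0.429), autophagy (3 of 10 lower and 1 higher, 0.0573) and the root genes (2 of 10 lower, 0.0722) were not called.

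Of the 1335 probe sets that rose in cold Col-0, both WS arrays lay above both 22 °C arrays for 1280 (95.9%), and of the 1386 that fell both lay below for 1322 (95.4%). Among as many probe sets with the highest and lowest limma t in simulations of unchanged groups, which share the 22 °C arrays too, these shares were 56.9% and 56.3% on average. The simulated probe sets were taken by t with no fold minimum and held no change. Their shares thus do not measure what probe sets that change in Col-0 would give without a response in WS. Median log2 folds were 1.44 in Col-0 and 1.41 in WS for the first, and -1.40 and -1.42 for the second. By limma 3227 probe sets were called in WS at 4 °C against Col-0 at 22 °C, 1551 higher and 1676 lower. Of these, 1010 were shared with the calls higher in cold Col-0 (independent lists give 91.0) and 1072 with the lower (102.1). Only 6 were called in opposite directions, among them AT4G23680, lower with cold in Col-0 (log2 -1.33) and higher in WS (log2 1.83), and CYP71B26, AT1G11280 and AT2G40010, higher in cold Col-0 and lower in WS (log2 -1.52, -2.81 and -2.15). The cold call of AT4G23680 ended without replicate 1 at 22 °C (adjusted p = 0.169), and that of AT1G11280 without replicate 3 of cold Col-0 (log2 0.93). Both contrasts used the same pair of 22 °C arrays. With Col-0 set against replicate 1 at 22 °C and WS against replicate 2, 1702 calls were shared in direction (independent lists give 177.3) and 14 were opposite, and with these exchanged 1607 (188.7) and 14. Correlations across probe sets were then 0.75 and 0.71. In 100 simulations of unchanged groups with shared arrays no call was shared, and the correlation across probe sets was 0.60, against 0.85 observed (covariance 0.027 against 0.495). Groups simulated without change give few calls, so the absence of shared calls follows from that setting. It does not measure what the shared arrays add to the overlap among probe sets that change. This contrast mixes accession and cold.

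**Figure D2:**
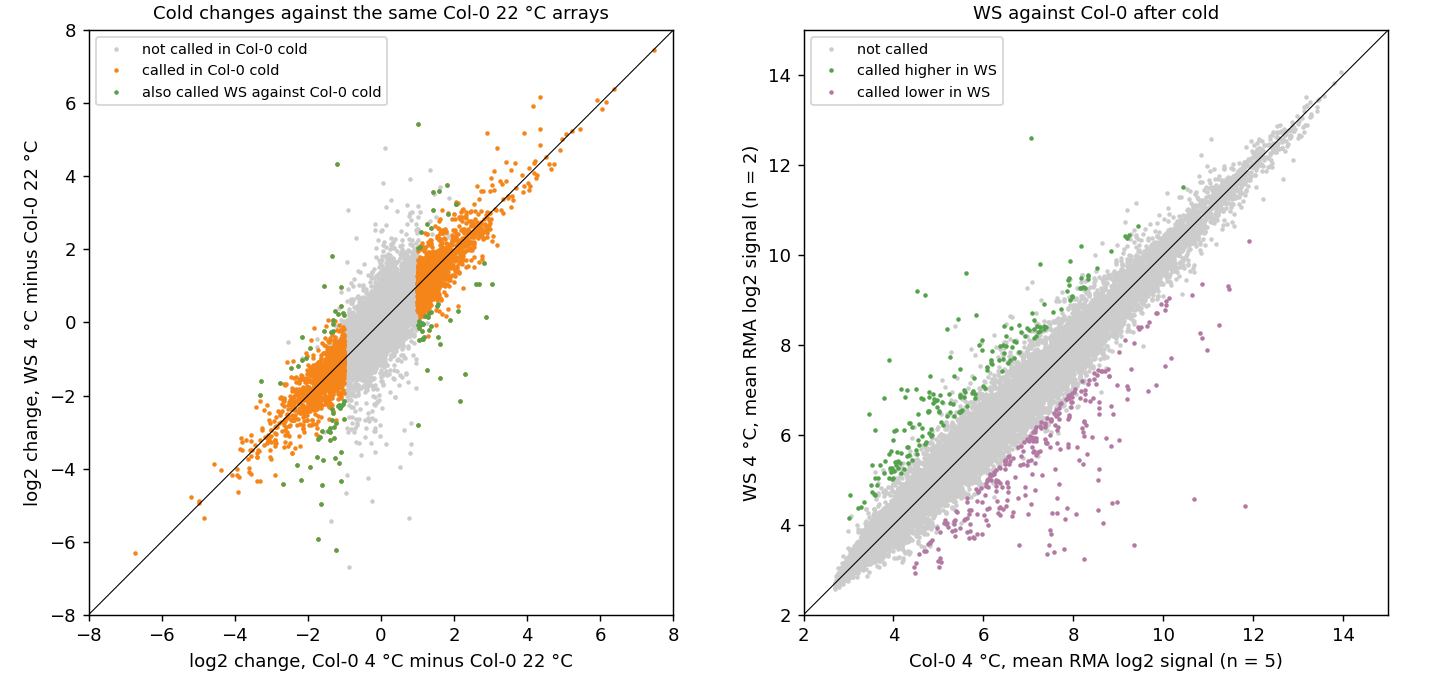
Left, log2 change in cold WS against that in cold Col-0, both against Col-0 at 22 °C, per probe set, with calls in colour. Right, mean RMA log2 signal in cold WS (n = 2) against cold Col-0 (n = 5). The changes on the left had a correlation of 0.85, with 0.60 in simulations of shared arrays, and on the right 195 probe sets lay higher and 291 lower in WS.

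Among genes called both with cold and between accessions, AT2G40010 rose in cold Col-0 from 5.63 ± 0.12 to 7.80 ± 0.21 and stood at 3.47 ± 0.27 in cold WS. ECS1 and AT3G47250 fell with cold in Col-0 (log2 -1.26 and -1.22) and were lower in cold WS than in cold Col-0. The WS signals of AT2G40010 (3.29 and 3.66) and AT3G47250 (3.34 and 3.11) were dim, so the sizes of these differences are uncertain. AT5G55050 rose 2.7-fold with cold in Col-0 and was 3.2-fold higher in cold WS than in cold Col-0. AT2G35820 and AT1G12080 fell with cold (log2 -1.09 and -2.15) and were higher in WS (log2 2.06 and 1.76), but the cold call of AT2G35820 ended without replicate 2 at 22 °C (adjusted p = 0.0698) or the first set 4 array (log2 -0.99). With no WS array at 22 °C, none of these WS differences can be read as a difference in cold response. They may be present without cold, or come from WS sequence that differs under the probes. Of 2721 cold-called probe sets, 104 (3.8%) also differed between the accessions, as against 382 of 20025 others (1.9%). Independent lists would share 58.1 (Fisher's exact test, two-sided, p = 2.85e-09). Probe sets from the same arrays are not independent of one another, so the Fisher p-values given here can overstate the evidence. Of the calls higher with cold, 13 were higher and 33 lower in WS, and of those lower with cold, 23 were higher and 35 lower, so 48 agreed in direction and 56 did not. Both contrasts use the cold Col-0 arrays, which pushes signs apart (correlation -0.29 in simulations of unchanged groups). With cold called on the arrays with no set name and WS compared with set 4, 34 agreed and 21 did not, and with the arrays exchanged 56 and 46. In the first of these, 55 were shared where independent lists give 29.9 (Fisher's exact test, two-sided, p = 6.76e-06), and without WS replicate 2 the 104 became 58.

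**Figure D3:**
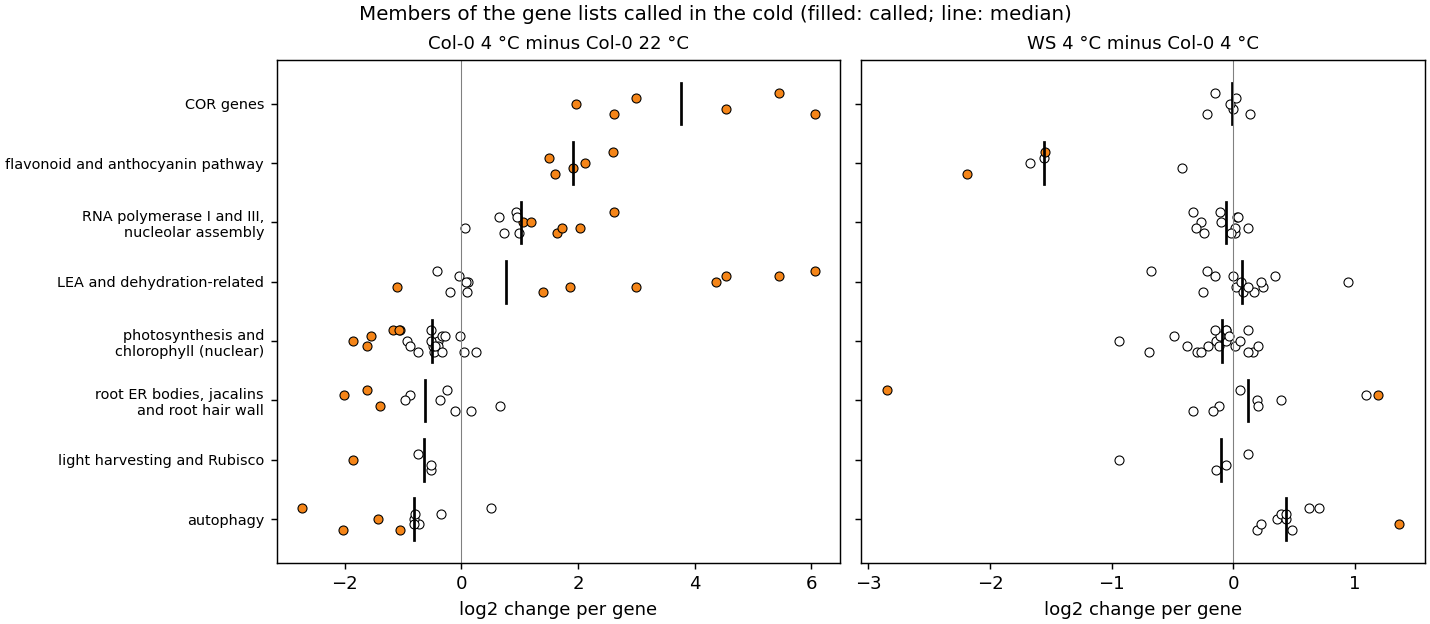
Log2 change of each measured gene in the 8 lists called in the cold, for Col-0 at 4 °C minus 22 °C (left) and WS minus Col-0 at 4 °C (right); filled points were called, and bars mark medians. COR genes had medians of 3.76 and -0.02, and flavonoid and anthocyanin genes of 1.92 and -1.56.

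The set 4 arrays were compared with the other cold Col-0 arrays as a measure of spread under the same treatment. COR15A differed by 0.03 and COR47 by -0.37 on the log2 scale, neither called, and no named gene was called. By limma 1 probe set was called, a probe set with no listed gene (log2 -2.30, SE 0.18, adjusted p = 0.0164), while 2401 (10.6%) had an unadjusted p under 0.05. There were 0 calls without replicate 1, 2 or 3 of cold Col-0, the first set 4 array or either WS array, and 2 without either 22 °C array. Camera called 4 lists lower in set 4 at an adjusted p of 0.0496: RNA polymerases I and III (median log2 -0.40), stomatal lineage (-0.41), plastid-encoded genes (-0.23) and nuclear photosynthesis genes (-0.14). With an estimated correlation the adjusted p = 0.864 for plastid-encoded genes and 0.749 for the other 3. None of the 4 was called without either 22 °C array (0.0633 or 0.0661) or replicate 1 of cold Col-0 (0.083 to 0.101), and the plastid list turned higher without the first set 4 array (0.286). Calls also ended without replicate 3 of cold Col-0 for the plastid list (0.147), without replicate 2 or the first set 4 array for photosynthesis (0.359 and 0.286) and stomatal genes (0.149 and 0.286), and without replicate 2, the second set 4 array or either WS array for RNA polymerases (0.051 to 0.354).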

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

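Of the tests in this part, only the one on brighter probe sets was chosen before its result was seen. All others on the 3 patterns were chosen after, and those on second probe sets of a gene were added once values were known. The spread of the 5 cold Col-0 arrays was tested for 117 values, and 11 had 1 array apart from the rest (gap over range above 0.71), where chance gives about 1 in 20.

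Cold Col-0 replicate 2 stood apart for AT1G51400 (ratio 0.732, at a log2 of 8.84 against 8.04 to 8.26), XTH20 (0.724, 7.39 against 8.31 to 8.66), XTH18 (0.724, 5.67 against 6.44 to 6.74), AOP3 (0.818, 3.55 against 3.81 to 3.87) and AT5G37980 (0.853, 4.62 against 4.88 to 4.93). The first set 4 array stood apart for GSTU18 (0.837, 6.01 against 5.87 to 5.89), TIL (0.764, 11.50 against 11.91 to 12.03), AUR1 (0.800, 6.34 against 6.85 to 6.97) and AUR2 (0.783, 5.95 against 6.54 to 6.71). Replicate 1 stood apart for THI2.1 (0.775, 3.69 against 3.49 to 3.54). The array median of cold Col-0 replicate 3 was 6.06 against 5.81 to 5.88 (0.722).

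Of the 486 probe sets called between WS and Col-0 after cold, 59.9% were lower in WS. Sequence in WS that differs under some of a gene's probes is a candidate explanation: among lower calls with a second probe set of the gene, 10.0% (1 of 10) were followed by it, as against 78.6% (11 of 14) of cold calls (Fisher's exact test, two-sided, p = 0.00276). Calls lower in the cold, the matching direction, were followed in 3 of 5 (Fisher's exact test, two-sided, p = 0.0769), so this stays open. All these counts are pairs of probe sets, and a gene with both called enters for each, so the Fisher p-values can be too small. That test covers few genes and calls close to the fold minimum, so it says little about ECS1 or HTB11. A share of 11.3% of lower calls had WS means among the dimmest Col-0 levels (under a log2 of 3.88), as against 9.7% in the mirrored count for higher calls (Fisher's exact test, two-sided, p = 0.654), so genes missing in WS stay open. With each array centred on its median 52.3% were lower, between the bounds set for an effect of scale and against it, and a difference in regulation between the accessions was not tested.

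Anthocyanin genes were lower in cold WS, with a list median of -1.56. The set 4 arrays differed from the other cold Col-0 arrays by 0.18 on this list (SD over members 0.24), and the WS median was -1.60 against the arrays with no set name and -1.70 against set 4, which argues against a set effect within Col-0 on average. The first and second set 4 arrays lay apart, at a log2 of 8.15 and 9.81 for AT4G14090, 8.80 and 10.56 for DFR, 7.85 and 9.60 for UF3GT and 6.68 and 7.92 for AT5MAT. For UGT78D2 they lay close, at 10.68 and 10.88. The set 4 average is thus imprecise, and the SD over members does not measure the spread between arrays. Probe mismatches in WS that strike genes one by one stay open, since 0 of the 5 list members had a second probe set of the gene with a Col-0 log2 signal of 6 or more. Cold WS was compared with set 4 for probe sets called in the cold on the arrays with no set name. The median log2 difference was 0.03 in the direction of the cold change (quartiles -0.23 and 0.30). Cold levels in WS thus did not fall short in general. A smaller cold response of WS as a whole stays open, because no mock-treated WS array was used and its starting levels are unknown. A growth batch of the WS plates stays open, as does a biological difference between accessions, and the list p of 0.571 with an estimated correlation, and single calls that depend on each WS array, leave the pattern itself a hypothesis.

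Cold-called probe sets differed between WS and Col-0 more often than others, with 104 shared calls. On separate cold Col-0 arrays 55 were shared, where independent lists give 29.9 (Fisher's exact test, two-sided, p = 6.76e-06, with probe sets taken as independent), which argues against the shared cold Col-0 arrays as the whole cause. Both fits still used the same 22 °C and WS arrays, so sharing through these arrays and their spread was not removed. Brighter probe sets may account for part: permuting cold calls within 20 bins of level gave 76.9 shared calls on average, above the 58.1 of independent lists, with a highest of 113 (one-sided permutation p = 4e-04). This permutation was not run on the separate arrays. The 55 thus have no level-matched number beside them, and their excess over 29.9 may be partly one of level. Probe sets that vary readily under any condition, and cold responses that differ between accessions, remain open and were not tested, since WS at 22 °C was not used here.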

How the results depend on the processing

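Leaving out arrays for the gene lists and shared calls, the exchange of cold Col-0 arrays between contrasts (102 shared calls, 58.2 for independent lists) and a different 22 °C array for each contrast (1702 and 1607 shared cold calls) were chosen after the data were seen, and the other alternatives were planned. Of 452 recomputed counts and list tests 359 kept their side of the threshold, or stayed within 1.5 times the reported count. Of 1734 values for named genes in the cold 1666 kept theirs, 61 lost and 7 gained a call; of 1113 for WS against Col-0 1029 kept theirs, 73 lost and 11 gained one. No gene changed direction and call together. With set 4 as the sole cold arrays, which are fewer, or with the replicate block and set 4 as a term, further calls ended, among them UF3GT (0.0548 and 0.065) and rpoB (0.122 and 0.131) in the cold, AT5MAT (0.234 and 0.155) and XTH18 (0.0788 and 0.0865) in WS against Col-0, and with set 4 alone Fes1A (0.051) in the cold and HTB1 (0.0558) in WS. Set 4 alone also gained GI in WS against Col-0 (0.0425) and ATSPS4F in the cold (0.0455), and PDF1.2 was gained in the cold without dim probe sets (0.035), with median centring (0.0456) or without set 4 (0.0294). Genes losing their call most often were JAL34, HIS1-3 and AT3G28220. Quantile normalization and median centring moved the median fold by at most 0.037 on the log2 scale, yet median centring gave 264 higher and 289 lower in WS against Col-0, so 52.3% were lower and not 59.9%. Signal over background was not assessed, which limits statements on dim probe sets. With 1 array left in a group, it is assumed to vary like the other groups.

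Without the fold minimum, which only admits more probe sets, there were 3180 higher and 3298 lower in the cold, 450 and 633 in WS against Col-0, 3097 and 3131 in WS at 4 °C against Col-0 at 22 °C, 4591 shared cold calls and 453 cold calls that differed in WS. With 1 probe set per gene, and so fewer tested, these contrasts had 713 and 731, 109 and 149, and 858 and 873, and the set contrast 0. With set 4 as the sole cold Col-0 arrays WS against Col-0 had 91 higher and 140 lower, and with set 4 left out 210 and 340. Both settings use fewer arrays, and the cause of the difference was not tested. The set contrast gave 0 with the compared arrays only, 2 with trend and robust eBayes and 2 with quantile normalization; the cause was not tested. Shared calls on separate cold Col-0 arrays were 55, and 102 with the arrays exchanged, both from fewer arrays.

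Leaving out each array in turn gave 1134 to 1459 higher and 1304 to 1440 lower in the cold, 111 to 231 and 174 to 319 in WS against Col-0, 1233 to 1645 and 1520 to 1759 in WS at 4 °C against Col-0 at 22 °C, 0 to 2 in the set contrast, 1850 to 2256 shared cold calls and 58 to 119 cold calls that differed in WS.

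With an estimated correlation, which widens the test by construction, adjusted p was 0.335 for all 8 lists called in the cold (COR, flavonoid, light harvesting, dehydration-related, autophagy, RNA polymerase I and III, photosynthesis, root genes), 0.571 for the flavonoid, autophagy and GSTU lists in WS against Col-0, and 0.38 for the 5 lists in WS at 4 °C against Col-0 at 22 °C. In the set contrast it was 0.864 for plastid-encoded genes and 0.749 for the RNA polymerase, photosynthesis and stomatal lists. Fry gave 0.057 for flavonoid and autophagy genes in WS against Col-0. In the set contrast fry gave 0.786 for plastid-encoded genes, 0.702 for photosynthesis and 0.689 for the RNA polymerase and stomatal lists. Without dim probe sets light harvesting had 0.0755 in the cold and 0.107 in WS at 4 °C against Col-0 at 22 °C, GSTU 0.245 in WS against Col-0, and in the set contrast plastid-encoded genes 0.277, RNA polymerase 0.277, photosynthesis 0.289 and stomatal 0.256; the cause was not tested.

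Leaving out each array gave list p-values in the cold of 2.3e-09 to 8.12e-06 (COR), 0.000283 to 0.00911 (flavonoid), 0.00776 to 0.0254 (light harvesting), 0.000209 to 0.00534 (dehydration-related), 6.36e-06 to 0.00121 (autophagy), 1.81e-07 to 1.07e-05 (RNA polymerase), 1.39e-07 to 9.2e-06 (photosynthesis) and 0.0093 to 0.0353 (root genes). In WS against Col-0 they were 8.56e-06 to 0.00216 (flavonoid), 3.98e-05 to 0.00119 (autophagy) and 0.0256 to 0.066 (GSTU), and in WS at 4 °C against Col-0 at 22 °C 2e-08 to 3.38e-05 (COR), 0.00995 to 0.0197 (light harvesting), 0.000146 to 0.00532 (dehydration-related), 8.34e-06 to 0.000209 (RNA polymerase) and 3.46e-09 to 8.7e-06 (photosynthesis). In the set contrast they were 1.33e-13 to 0.286 for plastid-encoded genes, the 0.286 with the direction reversed (without the first set 4 array), 0.00209 to 0.354 for RNA polymerase, 0.0092 to 0.359 for photosynthesis and 0.0118 to 0.286 for stomatal genes; the cause was not tested.

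Replicate numbers were not taken to pair the samples, since not every pair of arrays with the same number in different groups correlated above 0.1 (range -0.23 to 0.24). Centring makes the arrays of a pair mirror images, so these values repeat. Set 4 had 0.11 with 22 °C and 0.24 with WS, 22 °C had 0.09 with WS, and the cold arrays with no set name had -0.06 and -0.19 with 22 °C and -0.10 and -0.23 with WS. By the same centring, the 4 of 9 arrays that lay closest to one of their own number are only a hint. With the replicate number as a block and set 4 as a term, WS against Col-0 had 193 probe sets lower and 152 higher, and the cold contrast 1346 higher and 1475 lower; the cause was not tested.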

Other observations

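The test on neighbouring genes lower in WS was chosen before its result was seen, and the count of neighbours higher in WS was looked at after some of those genes had been seen.

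Among genes higher in cold WS than in cold Col-0, some were next to one another in the order of measured genes along a chromosome. Genes that were not measured may lie between them. AT1G52050, AT1G52060 and AT1G52070 were higher by a log2 of 2.04, 2.09 and 1.98, AT3G28310 by 2.04 and AT3G28320 6.5-fold, and AT5G37980, AT5G37990 and AT5G38020 by 1.31, 1.92 and 3.97. These made 5 pairs of neighbouring measured genes, where permuting the 110 higher genes over 13286 placed genes gave 0.9 on average (one-sided permutation p = 0.002, 100000 permutations). The permutation takes genes as exchangeable, and similar sequence among neighbouring genes was not examined. The call of AT1G52070 ended without either WS array, cold Col-0 replicate 2 or 3 or the first set 4 array (adjusted p = 0.0511 to 0.229), and that of AT5G37990 without WS replicate 1 (0.0684).

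A hypothesis was that divergent or missing segments in WS hold several neighbouring genes that are lower together. There were 3 such pairs of neighbouring measured genes among 151 lower genes (AT3G28200 and AT3G28220, AT4G13100 and AT4G13120, AT5G51620 and AT5G51630), against 1.7 on average in permutations (one-sided permutation p = 0.2). Leaving out WS replicate 2 ended at least 1 call of every pair: AT3G28200 (limma adjusted p = 0.0583), AT3G28220 (0.351), AT4G13100 (log2 -0.95), AT5G51620 (0.0803) and AT5G51630 (0.182). The call of AT3G28220 also ended without either 22 °C array, cold Col-0 replicate 1, 2 or 3 or the first set 4 array (0.0572 to 0.101), and that of AT5G51630 without the first set 4 array (0.0537) or WS replicate 1 (0.107). The test does not decide, because the count lies above the average without reaching the range that 5% of permutations exceed.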
